A study of Mus musculus with 4 samples.

How the data were processed

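Pro-B cells were sorted from Mb1-Cre control mice and Klf2 knockout mice, and poly(A) RNA was sequenced on an Illumina instrument, per the labels. The labels name a TruSeq kit and a NEBNext Ultra kit and do not say which library was made with which. CASAVA 1.8.2 and the mm10 genome are named per the submitters' processing notes, while the aligner, the counting tool and the annotation release are not given in the sources used here. The deposited table holds 38918 genes, of which 10534 have no exons in it.

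For each lane the authors deposited raw read counts per gene, split into gene, exon, exon-exon and intron-exon reads, each as unique and as total reads. They also deposited a signal, the median coverage of the exons. The authors deposited RPKM values, with their group means and signed fold, as a derived (other) unit. These RPKM equal total exon reads per kilobase of exon, scaled to the sum of total gene reads, with a largest difference of 0.0041 when recomputed.

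Unique exon reads were taken as the measure once the table had been seen, and total exon reads became an added alternative. Unique exon reads ranged from 3872769 to 6342388 per lane, and total gene reads were 11575769 and 11637350 in the control lanes and 14506949 and 14415402 in the knockout lanes. A floor of 3 reads equals 0.775 and 0.771 CPM in the control lanes and 0.473 and 0.476 CPM in the knockout lanes. The lanes of a group share a description label, so they were compared by an index of dispersion over genes with at least 20 reads. Chi-square per degree of freedom was 0.98 over 10367 genes in the control and 1.01 over 10901 genes in the knockout, so the lanes agree within sampling noise. On total exon reads it was 1.19 and 1.21. The lanes were therefore summed, each group counts as 1 library and no test between groups was made.

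Ratios are log2 of knockout over control CPM with TMM scaling from edgeR 4.0.16 and a prior count of 2. The intervals are exact conditional binomial 95% intervals of the ratio of reads, without the prior. A gene passed when its mean was at least 1 CPM, its ratio at least 2-fold, its interval left out no change, and every knockout lane lay on the same side of every control lane. The gene lists, 37 in all, the passing rule, the naming rule and the settings to be varied were fixed before the data were examined. A list's median over its members with at least 1 CPM was set beside 10000 random lists of the same size, matched in 20 bins of expression, as a description of these libraries, for the 36 lists with at least 3 such members. The interval of a median is the 95% interval over members. For the smallest lists it is the full range of the members and covers less than 95%. Named genes were the 12 highest and the 12 lowest passing genes with an official symbol, Klf2, and up to 4 members of each list with the largest absolute ratio. Unnamed and clone-derived loci and antibody segments were left out of that ranking.

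The procedure was tested on simulated data drawn as Poisson counts at the depth of these libraries, with no variation between preparations. Of 50 genes changed by each fold, 1 passed at 1.5-fold, 19 at 2-fold, 48 at 3-fold and 49 at 4-fold. The interval held no change for 95.7% of the unchanged genes. All 40 lists of genes shifted by 0.25 on the log2 scale were found, and 2 of 40 unshifted lists lay outside the random range.

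Alternatives were DESeq2 1.42.0 size factors, the total count alone, no filter, means of at least 5 or 10 CPM, a prior count of 0.5, a 1.5-fold threshold, each lane left out of both groups in turn, total exon reads, lists without members of other lists, and fits with edgeR and DESeq2 that took lanes as replicates. Those fits compare these libraries, not the conditions. Trends with GC content and exon length, taken from mouse GENCODE transcripts, were removed for 99.4% of the tested genes as a check. Settings meant for tables without counts (other pseudocounts and a limma fit) were not run. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.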

Results

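Polyadenylated RNA was sequenced from mouse pro-B cells, B-cell progenitors that were sorted as lineage-negative, CD19-positive cells with high CD43 and low B220. The control cells carried Mb1-Cre, a Cre recombinase expressed from the B-lineage gene Cd79a (Mb1), and the Klf2 knockout pro-B cells came from Klf2 Mb1-Cre mice, so both groups carried Cre per the labels. Each group was 1 library read on 2 sequencing lanes, so the 4 deposited samples stand for 2 libraries. The lanes held 3872769 and 3892869 unique exon reads for the control and 6342388 and 6304033 for the knockout. The comparison asked which genes depend on Klf2, a zinc-finger transcription factor, in B-cell progenitors.

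Klf2 itself was 3.0-fold lower in the knockout library, and few other well-expressed genes differed by as much. Fos and Fosb, which encode subunits of the AP-1 transcription factor, were higher in the knockout library, with log2 ratios of 2.05 and 1.34. Genes of mitosis and of DNA replication were lower by a small amount across nearly whole lists, with median log2 ratios of -0.21 and -0.14. Histone genes were lower by more (median -0.64), and so were class-switched antibody heavy-chain genes. The median of 5 other tested RNAs without a poly(A) tail was -0.63, with 3 of their intervals below 0. Intronic reads of long genes with hardly any exon read were lower as well (-0.90). NF-kappaB targets and genes of later B-cell stages were higher, with medians of 0.25 and 0.23, in a library where erythroid markers (0.49) and granulocyte and monocyte markers (0.31) were higher as well. With 1 library per group no spread between preparations was measured, so no test between the groups was made and every value describes these libraries.

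Klf2 lies on chromosome 8 from 72319033 to 72321656 in mm10 and has 3 exons. It had 375 and 377 unique exon reads in the control lanes and 217 and 192 in the knockout lanes, or 97.0 against 32.3 counts-per-million (CPM). The log2 ratio of knockout over control was -1.58, with an exact conditional binomial 95% interval from -1.76 to -1.41. This interval and the others for single genes cover counting error only, and not the spread between preparations. PCR copies are not independent molecules, so even the counting error may be understated. Spliced Klf2 reads, those across exon-exon junctions, were lower still, at 39 against 8 reads (-2.99, -4.30 to -1.87). Intronic Klf2 reads were not lower in the knockout library, at 263 against 505 reads (0.23, 0.02 to 0.45 on the scaling of exon reads). Reads across intron-exon boundaries were at 54 against 121 (0.46, -0.02 to 0.95), with 15 and 39 in the control lanes. Median coverage of the Klf2 exons in the authors' deposited table was 7 and 8 in the control lanes and 0 in each knockout lane. In the same deposited table the authors' mean RPKM of Klf2 was 17.5 against 7.66, a signed fold of -2.29. The labels do not say which part of the gene was deleted.

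**Figure D1:**
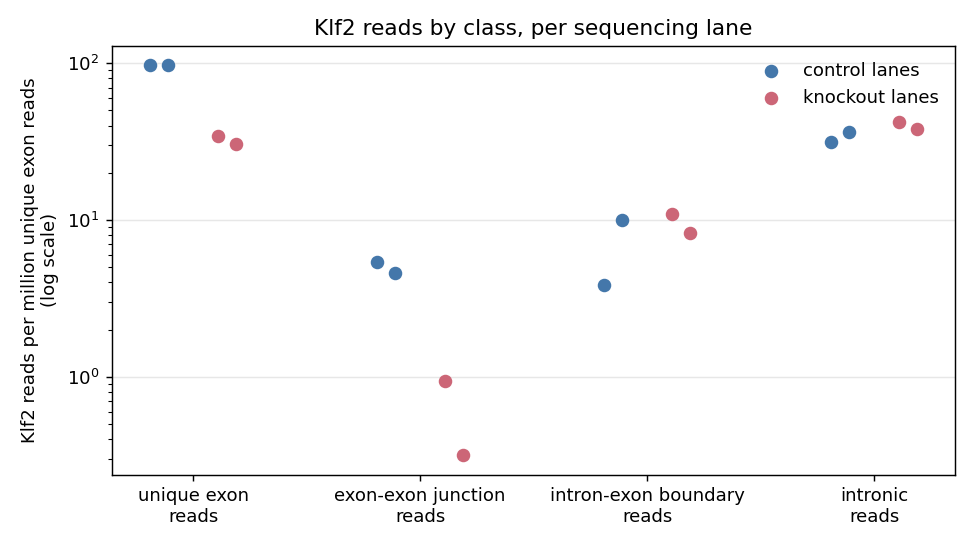
Klf2 reads in CPM of unique exon reads (log axis) in each of 4 read classes, with 1 point per sequencing lane. The knockout lanes lie below the control lanes in exon reads (32.3 against 97.0 CPM over both lanes) and exon-exon junction reads (0.632 against 5.03). They do not in intronic reads (39.9 against 33.9) or, over both lanes, in intron-exon boundary reads (9.55 against 6.96).

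Of 11473 genes with a mean of at least 1 CPM, 45 were at least 2-fold higher and 71 at least 2-fold lower in the knockout library with an interval that left out no change and every knockout lane on the same side of every control lane. For 94.6% of the genes the libraries lay within 1.5-fold of each other. Most of the passing genes were scarce, with 38 of the higher and 54 of the lower ones between 1 and 5 CPM. With 1 lane on each side, so with fewer reads and a lane criterion that adds nothing, the rule passed 57 genes between the control lanes. Between the knockout lanes it passed 47. On simulated libraries without any difference the full rule passed 42 genes, all 42 of them between 1 and 5 CPM. At 5 CPM or more, where the simulation passed 0 genes, 7 genes were higher and 17 lower, a level set after the data were seen. The simulation held counting noise only, so it does not show how many genes would pass between 2 preparations of the same cells.

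The genes higher at 5 CPM or more were Fos, Fosb, Lipc, Scn11a, Cr2, Gpm6b and the variable segment Ighv2-9. Lipc, which encodes hepatic lipase, had 286 control and 1157 knockout reads (1.30, 1.12 to 1.5). Scn11a, a voltage-gated sodium channel gene, was at 1.25 (0.74 to 1.86) and Gpm6b at 1.03 (0.45 to 1.73). The lower ones included Klf2, the histone genes Hist1h1e, Hist1h1d and Hist1h2ap, the antibody genes Igha, Ighg2c, Ighg2b and Igj, and Ppp3r1, a calcineurin regulatory subunit gene (-1.40, -1.93 to -0.95). Shank2 (-1.29), Maml1 (-1.08), Trp53rk (-1.06) and Fam104a (-1.74) were the other lower protein-coding genes with an official symbol. Few of the exon reads were unique for Fam104a (25.6%), Maml1 (20.3%) and Hist1h2ap (21.6%), and on total exon reads their ratios were -0.68, -0.43 and -0.68. Without the lane 2 samples Trp53rk was at -0.49, and without the lane 1 samples Hist1h1d was at -0.63. The remaining 4, Gm10800, Gm10801, Gm21738 and AY036118, are unnamed or clone-derived loci. Of these, Gm10800, Gm10801 and AY036118 are repeat-like or rRNA-like, so their reads need not reflect the expression of a gene. Lipc, Scn11a, Gpm6b, Ighv2-9, Ighg2b, Hist1h1d, Hist1h2ap, Ppp3r1, Shank2, Maml1, Trp53rk and those 4 loci were chosen after their values were seen.

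**Figure D2:**
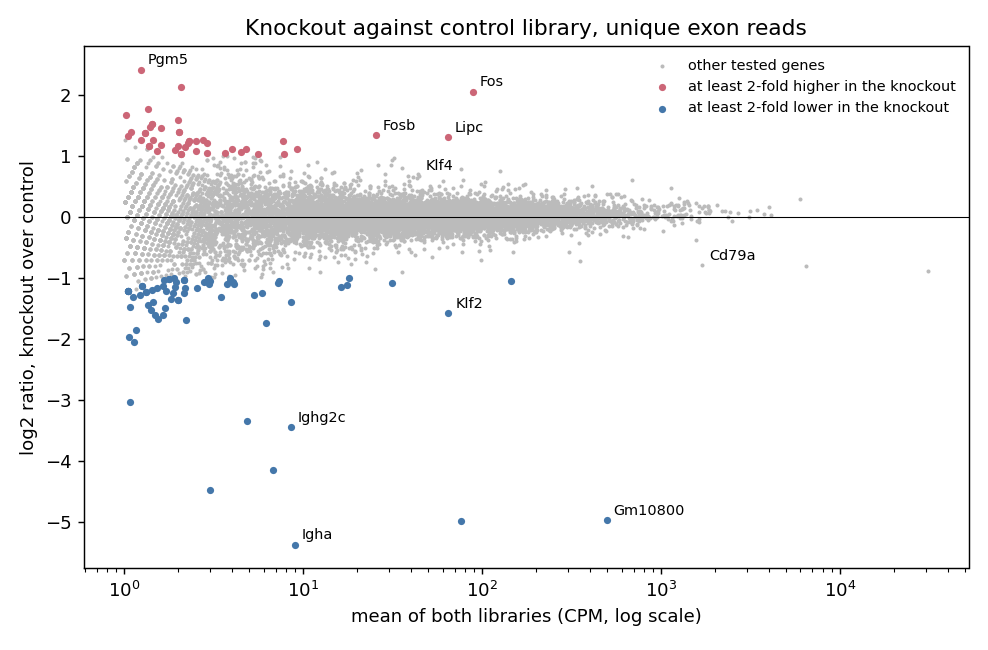
Log2 ratio of knockout over control against the mean of both libraries in CPM (log axis), with 1 point per tested gene and colours for genes passing the 2-fold rule in either direction. Most coloured points lie below 5 CPM. Fos (2.05), Fosb (1.34), Lipc (1.30), Klf2 (-1.58), Igha (-5.37) and the repeat-like locus Gm10800 (-4.97) stand apart from well-measured neighbours.

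Ranked by size, the higher genes were led by Pgm5, a phosphoglucomutase relative, at 2.41 from 2 control and 28 knockout reads (interval 1.11 to 6.21), followed by Fos. Frs3 (1.76), Itgb2l (1.67), Hepacam2 (1.58), Efcab12 (1.52), Slc22a12 (1.52), Il9r (1.45), Slfn1 (1.38), Trpm5 (1.38), Rab30 (1.38) and Slc47a1 (1.37) came next, none with more than 8 control reads. Among the lower genes Col25a1, a membrane collagen gene, came to -3.04 from 16 control reads and 1 knockout read (-10.10 to -2.02). Ctla2a (-2.06), Hist1h2bm (-1.97), Hist1h2ag (-1.85), Fam104a, Glis2 (-1.69, but -0.27 without the lane 1 samples), Grin3a (-1.68), Ttll9 (-1.61), Fbxo47 (-1.60), Klf2, Podnl1 (-1.53) and Cds1 (-1.49) followed. Apart from Fos, Klf2 and Fam104a, these 24 genes had a mean below 5 CPM, the range in which simulated libraries without a difference also passed genes.

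Immediate-early genes, which respond to stimulation within minutes, did not move as a group: 14 of 26 tested members were higher and 12 lower, with a median of 0.07. Fos had 267 control and 1808 knockout reads (2.05, 1.87 to 2.24) and Fosb 111 and 462 (1.34, 1.05 to 1.66), and these 2 were the members that passed. Cd83, a B-cell activation marker, was at 0.73 and Ier3 at -0.71. Other classical members, picked after their values were seen, were at 0.45 (Jun), 0.32 (Junb), 0.15 (Egr1) and -0.42 (Nr4a1).

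All 34 tested genes of the G2/M list were lower in the knockout library, 26 of them with an interval below 0. Their median was -0.21 (95% interval over members -0.23 to -0.14), and 0% of 10000 random lists of like expression lay lower. Mki67, the proliferation marker Ki-67, was at -0.38 (-0.41 to -0.35), Cenpe, a kinetochore motor gene, at -0.37, and Aurka, a mitotic kinase gene, at -0.33. Of 44 S-phase and replication genes 43 were lower, with a median of -0.14 (-0.20 to -0.12), also below the random lists. The cyclin E genes Ccne1 (-0.49) and Ccne2 (-0.40), the clamp-loader subunit gene Rfc4 (-0.39) and the checkpoint gene Clspn (-0.35) were the lowest. No member of either list passed the 2-fold rule. Cell-cycle inhibitor genes had a median of -0.09, with 10 of 16 lower, and Cdkn2d was at -0.30.

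The histone list was lower in 20 of 22 tested cases, with a median of -0.64 (-0.91 to -0.16), and 5 passed. It holds the variant genes H2afx (-0.16) and H2afz (-0.12), without which the median of the other 20 was -0.68 (-0.91 to -0.34), a set formed after the values were seen. Hist1h4c (-1.32), Hist1h3c (-1.17) and Hist1h1e (-1.12, from 186 to 138 reads) were lower, and Hist1h1c, picked after its value was seen, was higher at 0.46 (0.34 to 0.58). Other RNAs without a poly(A) tail, counted by unique gene reads on the scaling of exon reads, had a median of -0.63 over 5 tested genes. Of these 3 had an interval below 0. On that scaling intronic reads of long genes with at most 3 total exon reads had a median of -0.90. Whether the source of these intronic reads carries a poly(A) tail was not tested.

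Constant-region genes of switched antibodies were lower in the knockout library, by unequal amounts. Igha, the IgA constant gene, had 137 control reads and 3 knockout reads (-5.37, -8.52 to -4.64). Ighg2c had 122 and 16 (-3.45), Ighg1 70 and 9 (-3.35), Ighg2b, with the most reads, 175 and 128 (-1.14, -1.50 to -0.82), and Igj, the joining chain of secreted antibodies, 65 and 43 (-1.26). The plasma-cell list that holds these genes had a median of -0.09, with 5 of 12 members higher and 7 lower.

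Genes of later B-cell stages were higher in 27 of 30 tested cases, with a median of 0.23 (0.13 to 0.32) above nearly all random lists (percentile 100). Cr2, the complement receptor CD21, was at 1.11 (45 to 161 reads), Fcer2a, the IgE receptor CD23, at 0.65, and Bank1, a B-cell scaffold gene, at 0.63. The mature B-cell markers, 10 of 11 of which also stand in other lists, had a median of 0.31, and the small pre-B genes 0.16, with Cd22 at 0.34 and Igkc at 0.32. All 19 small pre-B genes and 15 of the 30 later-stage genes stand in other lists too, so these lists are not separate evidence. NF-kappaB targets were higher in 15 of 17 cases, with a median of 0.25 (0.09 to 0.31), led by Traf1 (1.03, 10 to 36 reads), Nfkb2 (0.54) and Bcl3 (0.35). In the same library markers of other blood cells were higher as well, the erythroid list by a median of 0.49 (0.26 to 0.72) and the granulocyte and monocyte list by 0.31 (0.12 to 0.42).

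The pre-B-cell receptor and its signalling genes had a median of 0.05, inside the range of random lists, with 16 of 23 higher. Cd79a, the receptor's signalling chain and the locus from which Mb1-Cre is expressed, was the lowest at -0.80 (-0.83 to -0.77), with 16573 control and 15563 knockout reads. Its exon-exon junction reads were at -0.81. Whether both groups carried the same number of Cre copies at this locus was not tested. Of the 7 lower members 4 had an interval below 0, the others being Rasgrp1 (-0.49), Vpreb1 (-0.21) and Igll1 (-0.11), while Cd79b and Cd19 were at 0.22 and 0.23. Igll1, Cd79b and Cd19 were picked after their values were seen. B-lineage transcription factors had a median of 0.05, with Pou2f2, the gene of OCT2, at 0.43 and Spi1, the gene of PU.1, at 0.27. V(D)J recombination genes (-0.01), interleukin-7 receptor signalling (0.02) and PI3K-FOXO1 targets (0.03) likewise lay inside the random range. Within them Dntt, the terminal transferase, was at -0.20 and the kinase gene Pim2 at 0.49.

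Trafficking and adhesion genes, a class known to depend on KLF2 in lymphocytes, were higher in 13 of 19 cases, with a median of 0.08 (-0.17 to 0.29). None passed, and the ends were S1pr3 at 0.71 and S1pr4 at -0.58. S1pr1, the receptor for egress from tissues, was at 0.29 (0.12 to 0.46), and Sell, the L-selectin gene, picked after its value was seen, at 0.20. The KLF family had a median of -0.07, in which Klf4 was at 0.67 (264 to 689 reads), Klf10 at -0.29, and Klf2 was the member that passed.

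**Figure D3:**
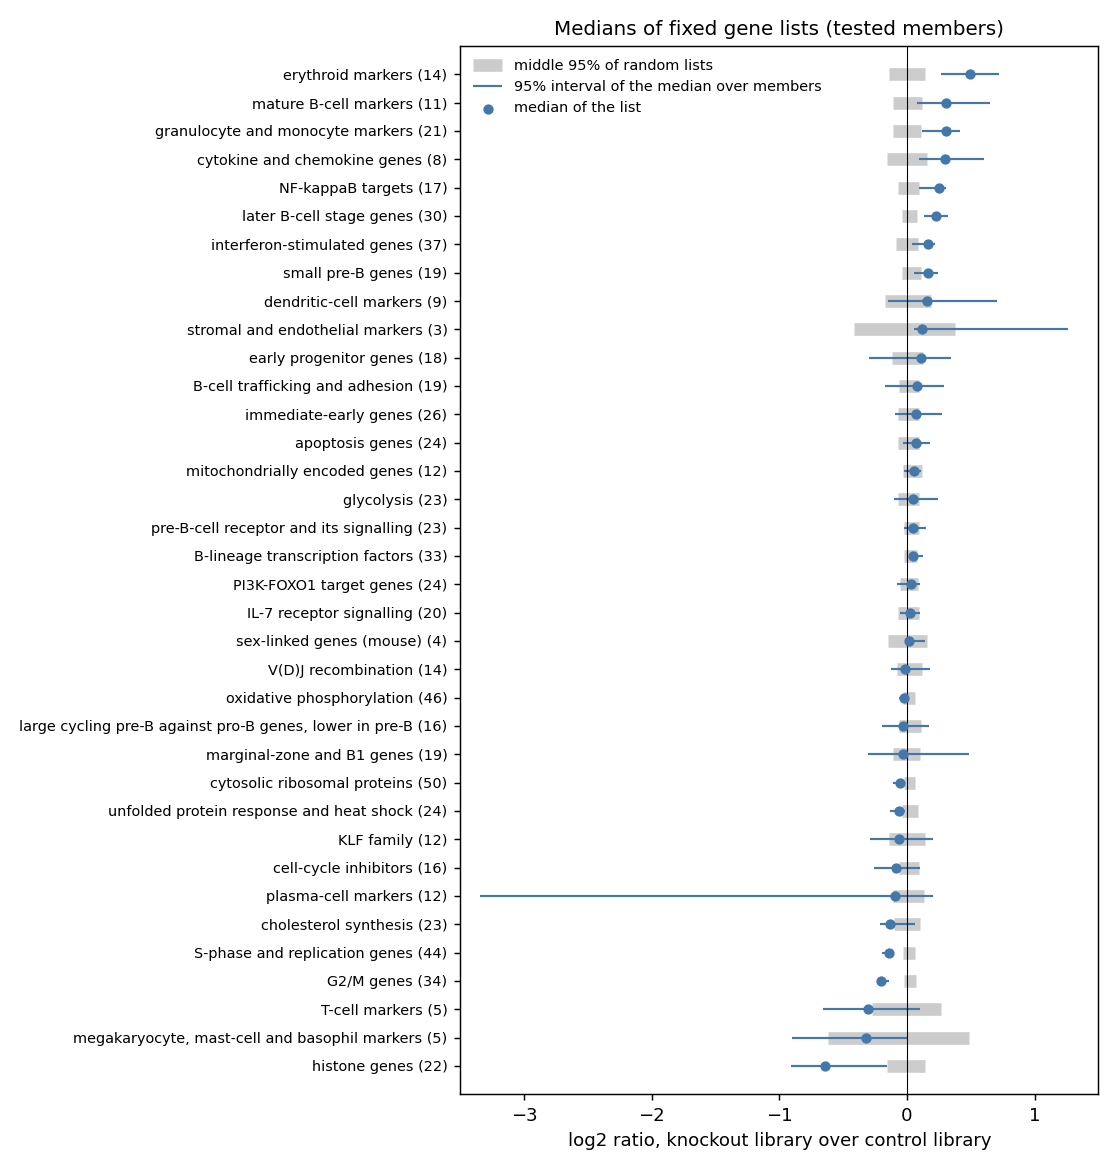
Median log2 ratio of each gene list with at least 3 tested members (number of tested members in brackets). Lines give the 95% interval of the median over members, or the full range of the members for the smallest lists. Grey bars give the middle 95% of 10000 random lists of like expression. Of 36 lists, 8 lie below the grey bars and 8 above, where chance among independent genes would put 1.8. The cycle lists are narrow and low, while the erythroid list is highest at 0.49.

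The libraries also differed in make-up. Exon reads were 48.4% of the control's unique gene reads and 58.5% of the knockout's. The repeat-like locus Gm26924 alone held 2692293 of the control's 8273741 other unique gene reads and 1874045 of the knockout's 8980104. The RPKM of the authors' deposited table divides by exon and intron reads together. Its median log2 ratio over the tested genes was 0.40, and 93.6% of them were higher in the knockout, against 52.0% after scaling on exon reads. Gm26924, Cmss1, Jarid2, Lars2 and Zc3h7a together held 29.5% of the control's total gene reads and 18.0% of the knockout's. How far these loci account for the RPKM shift was not tested. The Y-linked genes Ddx3y and Eif2s3y were at -0.01 each, and Xist had 1 read in each library.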

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

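The tests of the share of B-lineage cells, the share of early pro-B cells, poly(A) selection, S-phase cells, plasma cells and, with H2afx and H2afz left out, reads shared between histone genes were chosen after the results were seen, and Ckap2 and Cdt1 were picked after their values were seen. The tests of GC content, exon length and, for the antibody genes, shared reads were written before their results were seen, although total exon reads were taken up only after the table was.

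Intronic reads, which the comparison of exon reads does not use, were at least 2-fold higher in the knockout library for 10 of 7818 genes with at least 100 such reads, on their own scaling. Fos (2.16), Fosb (1.37), Lipc (1.07) and Scn11a (1.08) were among them and also passed in exon reads. Klf4, a relative of Klf2, was at 1.38 in introns and 0.67 in exons. The others were Gm12913 (2.03), Ak8 (1.5), Me3 (1.14), Oas1a (1.12) and Fam213a (1.06). In the other direction 21 genes were at least 2-fold lower, 5 of which passed in exon reads. They included the unnamed loci Gm26870 (-4.63), Gm21738 (-4.38), Gm10801 (-4.20) and Gm26924 (-1.09). Others, such as Chl1 (-3.62), Ptprd (-2.03) and Lrp1b (-1.90), were below the level filter in exon reads. The 21 need not be genes with lower transcription.

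Genes of mitosis and DNA replication were lower in the knockout library by a small amount that differed between members, from Mki67 at -0.38 to Ckap2 at -0.01 and from Ccne1 at -0.49 to Cdt1 at 0.02. With the trends in GC content and exon length removed, the medians stayed at -0.20 (-0.22 to -0.14) for G2/M and -0.15 for S phase, which argues against those trends as the whole cause. A lower share of B-lineage cells would lower the pre-B-cell receptor genes as much, and their median was 0.05 (-0.02 to 0.15). A lower share of early pro-B cells cannot be told apart. The genes lower in large cycling pre-B than in pro-B cells had a median of -0.03, with an interval (-0.20 to 0.17) that reaches the cycle genes. That list sets pro-B cells against another cycling stage, so it cannot address a shift towards non-cycling cells. Genes of later B-cell stages (median 0.23, 27 of 30 higher) and small pre-B genes (0.16, 15 of 19) were higher in the knockout library. Whether a larger share of such cells went with the lower cycle genes was not tested. An effect of Klf2 loss and a difference between single preparations, including in their mix of B-cell stages, go with the groups and stay open. So does a difference of library kit, if there was one, since the labels do not say which kit made which library. Whether the groups differed in the number of Cre copies at Cd79a was not tested, and that stays open too.

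Histone genes other than the variants H2afx and H2afz had a median of -0.68 on unique exon reads (-0.91 to -0.34). Counted with shared reads it was -0.70 (-1.06 to -0.41), over 27 genes and below the random lists, which argues against reads shared between histone copies. Less complete poly(A) selection in the control library is a candidate explanation that these values cannot decide. Of 28 other RNAs without a poly(A) tail 5 had enough reads to test. These were lower in the knockout, with a median of -0.63 (members from -0.81 to -0.17) and 3 intervals below 0 (Rmrp, Rpph1 and Rn7sk). Among the untested ones Rnu11 had 0 control and 7 knockout reads and Rnu12 had 0 and 3. However, 0 of the 28 had a unique exon read. On the same scaling intronic reads of long genes with at most 3 total exon reads, a set chosen after the values were seen, were at -0.90. Whether the source of these intronic reads carries a poly(A) tail was not tested, so they count neither for nor against this explanation. AY036118 and Gm26924, repeat-like or rRNA-like loci picked after their values were seen, were lower too. AY036118 was at -1.06, and Gm26924 took 12.6% of the control's total gene reads and 7.09% of the knockout's. The S-phase median of -0.14 (-0.20 to -0.12), or -0.16 (-0.18 to -0.12) with shared reads, lies above the histone interval on either count, which argues against a fall in S-phase cells that lowers both lists alike. A partial contribution stays open, because replication genes are also transcribed outside S phase, and so does Klf2 loss itself, untested. A difference of library kit, if there was one, stays open as well, since the labels do not say which kit made which library.

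Class-switched constant genes were lower, with Igha at 3 knockout reads where the control's level would give 224. The unique share of their exon reads was 100% for Igha and Ighg1, 95.2% for Ighg2c and 88.3% for Ighg2b. So few shared reads argue against reads shared between antibody genes. On total exon reads 4 of 4 genes kept an interval below 0, though with so few shared reads that count could hardly change. Fewer plasma cells in the knockout sort may account for the lower constant genes, since Igj was at -1.26 (-1.89 to -0.73). This cannot be told apart, because 7 plasma-cell markers outside the antibody genes had a median of 0.17 (-0.16 to 0.31), and pro-B cells express several of these at levels that would hide a small share. The sort would remove plasma cells that had lost CD19, whereas high CD43 and low B220 are shared with plasma cells, and an effect of Klf2 loss stays open.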

How the results depend on the processing

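The filter at 5 CPM, total exon reads and the histone list without variants were chosen after seeing the data. The Klf2 level per sample, as a log2 ratio, stayed inside its counting interval under all 6 alternatives, from -1.66 to -1.50. The 45 higher genes became 7 at 5 CPM, 3 at 10 CPM and 132 at 1.5-fold, and the 71 lower ones 17, 8 and 180, with 66 higher and 136 lower without a filter, as fewer or more genes could pass. With lanes taken as replicates edgeR called 592 higher and 488 lower, with the lane as a block 673 and 559, and DESeq2 261 and 159, at an adjusted p of 0.05 and any fold; at 2-fold or more these were 20 and 45, 26 and 47, and 2 and 4. The other scalings kept the same 45 and 71 genes. Single lanes gave 48 to 54 higher and 76 to 95 lower, but of the 45 higher genes 18 and 18 were shared, and of the 71 lower ones 43 and 30, and total exon reads gave 64 higher and 102 lower, with 37 and 53 shared. Among named genes 1062 of 1080 values stayed inside the counting interval. Without the lane 1 samples Glis2 went from -1.69 to -0.27, and on total exon reads Pgk1 went from 0.84 to 0.05, Fam104a from -1.74 to -0.68 and H2afz from -0.12 to -0.31. Trp53rk went from -1.06 to -0.49 without the lane 2 samples and Card11 from 0.25 to 0.06; the cause was not tested. For lists 352 of 355 medians stayed inside their interval, PI3K-FOXO1 targets went from 0.03 to 0.11 without the lane 2 samples, and the T-cell markers turned from -0.31 to 0.025 at 5 and at 10 CPM, where fewer members are left. Below 5 CPM the depth limits what a 2-fold ratio can show. The pseudocounts and the limma fit planned for tables without counts were not run, since counts were there.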

Other observations

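Interferon-stimulated genes had a median of 0.17 (0.04 to 0.22), with 26 of 37 higher and none passing, Oasl2 at 0.67 and Samd9l at -0.53. All 8 tested cytokine and chemokine genes were higher, with a median of 0.30 and Ltb, the gene of lymphotoxin beta, at 0.60. Apoptosis genes had a median of 0.07, with the p53 target Bbc3 at 0.56. Marginal-zone and B1 genes went both ways around -0.03, with Bhlhe41 at 0.77, and early progenitor genes around 0.11, with Hoxa7 at 0.69. Cholesterol synthesis genes had a median of -0.13, with 16 of 23 lower and Hmgcs1 at -0.26. Genes of the unfolded protein response and heat shock were lower in 19 of 24 cases, with a median of -0.06, and cytosolic ribosomal protein genes in 39 of 50, with a median of -0.05. Oxidative phosphorylation (-0.02), glycolysis (0.05) and mitochondrially encoded genes (0.05) lay inside the range of random lists, as did the Y-linked genes (0.02).

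Markers of other cell types were measured although the sort removed lineage-positive cells. Among erythroid genes Car1 was at 1.07 (22 to 78 reads) and Hba-a2, an alpha-globin gene, at 0.72 (117 to 316 reads), and in the granulocyte and monocyte list Ly6c2 was at 0.70. Dendritic-cell markers had a median of 0.15 and stromal and endothelial markers 0.12 over 3 genes. T-cell markers had a median of -0.31 over 5 genes, which turned to 0.025 at 5 CPM, and megakaryocyte, mast-cell and basophil markers -0.32 over 5 genes, with every member's interval holding 0. Only 2 NK-cell markers reached 1 CPM, so that list has no median.

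Repeat-like loci and intronic reads also differed between the libraries. Gm26924 took 12.6% of the control's total gene reads and 7.09% of the knockout's. Gm10800 had 7435 control and 385 knockout unique exon reads. In 238 genes of at least 200 kb with at most 3 total exon reads and at least 20 intronic reads, a set chosen after the values were seen, the median intronic log2 ratio was -0.90 on the scaling of exon reads (-1.0 to -0.81), and 222 were lower in the knockout library. Intronic reads of Cd79a were at -0.29 on the same scaling (-0.42 to -0.16), against -0.80 in its exons.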
